A study of Mus musculus with 48 samples.

How the data were processed

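RNA of sorted mouse endothelial cells was sequenced in 48 libraries of 10 groups, a TdTomato+ and a TdTomato- fraction of each of 5 combinations of tissue and age. Groups and replicate numbers were taken from the source names in the labels. Per the labels, tissues were digested with collagenase, stained for CD31, CD45 and Ter119 and sorted by flow cytometry. RNA was then isolated with a column kit for small samples. The labels and the run sheets name different library kits, an RNA capture kit with poly(A) selection in the former and a full-length cDNA kit for low input in the latter, with 1 ng and 0.7 ng of RNA in the 2 sequencing runs. Because the kit and the strand setting of the counting are not settled in the sources used here, values of overlapping and antisense genes are uncertain, as are those of genes with near-identical copies.

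The authors deposited raw read counts per gene for 15569 genes, together with their own comparisons. Reads were aligned with STAR and counted with featureCounts on the mouse genome build mm10, per the submitters' processing notes, which give no versions. The gene filter behind the table is not given in the sources used here. The lowest total of a listed gene over all libraries was 56 counts, so values of rarer transcripts are not analysed here. The authors' comparisons give a log2 fold change and a false discovery rate, an adjusted p-value, for each gene in 11 deposited contrasts, made with edgeR per the submitters' processing notes. Deposited mapping statistics give read numbers per mapping class, and the run sheets give the RNA integrity number, a score of RNA degradation, for each library, per the file headers. Coordinates are those of the deposited table, on mm10. The sheets also list 2 columns of other samples, which were not used here.

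Total counts of the 48 libraries were 17512843 to 27622937, and 81.2 to 90.1% of reads mapped uniquely in the 46 libraries of the joint model. Mitochondrial reads made up 0.28 to 5.01%, and the RNA integrity number ran from 3.6 to 10. No molecular identifiers are named in the labels, so counting intervals and floors cover counting error only. No 2 libraries held identical values, and replicates of 1 group differed by at least 14.8 in chi-square per degree of freedom, far above sampling noise. The labels do not say whether a replicate is 1 animal or a pool, so p-values measure the spread between these samples, part of which may be technical. Both libraries of P1 heart pair 5 held at least 10 CPM of Xist and of Ddx3y RNA, marks of female and male cells. A pool of both sexes would give this.

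The design, the alternatives, the 30 gene lists and the rule for named genes were fixed before the data were examined. The joint model held 46 libraries. It left out P1 heart pair 1, whose TdTomato+ library the labels record as failing quality control. Counts were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 (R 4.3.3), and filterByExpr removed 12 genes, leaving 15557. A quasi-likelihood negative binomial model held each matched pair as a replicate block and 1 TdTomato+ effect for each combination. The contrasts were the 5 effects, their mean, their equality, and the age differences of the effect in heart and in muscle. Age was compared within a fraction over the 23 libraries of that fraction, with no block. Benjamini-Hochberg adjusted p below 0.05 was called. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. Log2 CPM per library used a prior count of 2.

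The pairing comes from the labels, which call libraries with the same tissue, age and number matched. It was checked on the deviations of 7727 genes from their group means. Correlations between partners ran from -0.03 to 0.68 (median 0.32), above 0.1 in 22 of 23 pairs, and in 19 of 23 pairs the libraries matched their own partner best. The exceptions were P6 muscle pairs 2, 4 and 5 and 6W heart pair 4. RNA of sex-linked genes agreed within all 23 pairs. This does not test the pairing in P6 muscle, where every library held Ddx3y RNA, nor among P1 heart pairs 2 to 4, which all held Xist RNA. Since P6 muscle pair 5 stood at -0.03, counts without the block are given beside the paired ones.

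Named genes were Abcg2, the 6 genes with the largest rise and the 6 with the largest fall among those called, at 10 CPM or more on average and with the same sign in every pair, and up to 2 called members of each list with the smallest p. The mean effect took 10 and 10 genes with 1 sign in all 5 combinations, the age differences of the effect 5 and 5, and the age comparisons 6 and 6 with groups that do not overlap. Unnamed transcripts were skipped, and 2 genes that the rule takes are not reported here. Of the 579 genes of the lists, 564 were in the table. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 30 lists. The lists hold markers of other cell types that a sort could carry over. Where a group held no count of a gene, folds are bounds against a floor of 3 counts over the group, and groups with 1 to 3 counts have exact 95% counting intervals. The mean effect and the age differences of the effect were not bounded in this way.

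The fits were tested on simulated counts for 15295 genes (14578 to 14613 in the age comparisons) with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. Genes were drawn independently, each with 1 spread for all libraries. The recovered shares therefore leave out differences in spread between combinations, and camera was not tested on correlated genes. Of genes changed 2-fold and 4-fold, 65% and 82% were recovered in P1 heart, 69% and 85% in P1 lung, 67% and 81% in P6 muscle, 70% and 89% in 6W heart, and 69% and 79% in 6W muscle. In the age comparisons the 2-fold share was 53 to 64% and the 4-fold share 75 to 80%. The test of equal effects recovered 69.8% of the changed genes, the mean effect 49.9%, and the age differences of the effect 68.4% in heart and 64% in muscle. Camera found a planted list of 20 genes in simulated P6 muscle (adjusted p = 1.34e-28, and adjusted p = 8.54e-09 with an estimated correlation). It also called 1 of the 30 fixed lists, which were not planted but may hold some of the changed genes.

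Alternatives were scaling by DESeq2's median ratios in the edgeR fit, no filter on low counts, DESeq2 1.42.0 on the same design, no replicate block, P1 heart pair 1 included, 6W heart pairs 5 and 6 left out because 1 of their labels names muscle, fits of 1 comparison alone, and each pair left out in turn. Added after seeing the data were the RNA integrity number, the pericyte marker level and the lung epithelium marker level as covariates, and 6W heart pairs 1, 2 and 4 or 6W muscle libraries 3 and 4 left out.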

Results

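RNA sequencing compared endothelial cells that had expressed Abcg2, a drug efflux transporter of the ATP-binding cassette family, with the other endothelial cells of the same tissue. Mice carried a tamoxifen-inducible Cre recombinase under Abcg2 control and a Cre-activated TdTomato reporter, and were injected with 50 mg/kg tamoxifen 24 h before dissection. Cells with the endothelial surface protein CD31 and without the blood cell proteins CD45 and Ter119 were sorted into a TdTomato+ fraction, named vascular endothelial stem cells by the submitters, and a TdTomato- fraction, named mature endothelial cells. The tissues were heart and lung at postnatal day 1 (P1), skeletal muscle at postnatal day 6 (P6), and heart and muscle at 6 weeks (6W). Of 48 libraries in 10 groups, pair 1 of P1 heart was left out because the labels record its TdTomato+ library as failing quality control. The remaining 46 libraries formed 23 matched pairs, 5 each in P1 lung, P6 muscle and 6W heart and 4 each in P1 heart and 6W muscle. Their total counts ran from 17512843 to 27622937, and 13048 to 14973 genes had at least 1 count.

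RNA integrity was lower in the TdTomato+ than the TdTomato- library in 4 of 4 pairs of 6W muscle (mean difference -2.12, SD 0.66, n = 4). The mean difference was -1.85 in P1 heart, -0.92 in 6W heart, -0.78 in P1 lung and -0.34 in P6 muscle. In none of the 5 tissue and age combinations did the exact sign-flip permutation test (two-sided) reach p = 0.05, and the smallest p it allows is 0.125 with 4 pairs and 0.0625 with 5. TdTomato+ libraries of P1 heart also held fewer genes with a count than their partners in 4 of 4 pairs (mean difference -821 genes).

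Abcg2 (mm10 chromosome 6, 58596672 to 58692451, plus strand), the gene that drives the reporter, was measured first. Its level was 1.39-fold higher in TdTomato+ cells of P1 lung (83.2 ± 10 against 59.9 ± 3.5 CPM, the read count scaled to library size by TMM, mean ± SD, n = 5) and 1.29-fold higher in P6 muscle (147 ± 9.2 against 114 ± 11 CPM, n = 5). Both passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p = 0.00111 in P1 lung and 0.0414 in P6 muscle. The P6 muscle call was lost when any 1 of its 5 pairs was left out (log2 fold change 0.34 to 0.42). In 6W heart Abcg2 stood at 221 ± 23 CPM in TdTomato+ and 189 ± 12 in TdTomato- cells (n = 5), and in 6W muscle at 328 ± 35 and 278 ± 50 (n = 4). Neither difference passed the test (log2 fold change 0.23 ± 0.09, SE, adjusted p = 0.282, and 0.24 ± 0.10, adjusted p = 0.188; edgeR quasi-likelihood, Benjamini-Hochberg). In P1 heart the levels were 117 ± 25 and 112 ± 5.7 CPM (n = 4), a log2 fold change of 0.03 ± 0.10 that turned when CPM was scaled by total count alone (121 against 125). Averaged over the 5 combinations, Abcg2 was higher in TdTomato+ cells by a log2 fold change of 0.27 ± 0.04 (adjusted p = 0.000243, edgeR quasi-likelihood, Benjamini-Hochberg).

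**Figure D1:**
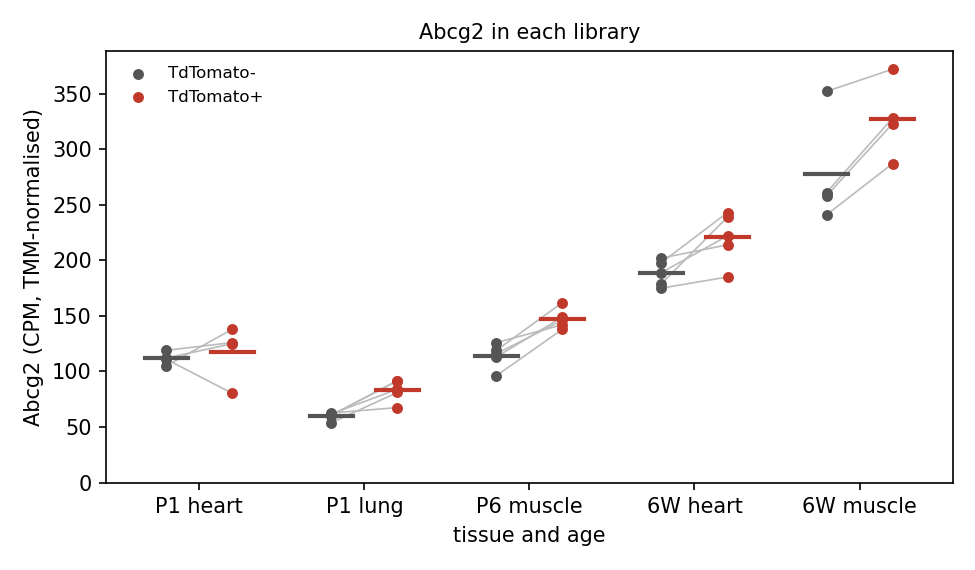
Abcg2 in CPM, normalised by trimmed mean of M values, in each of the 46 libraries. Points joined by a line are a matched pair and horizontal bars are group means; P1 lung TdTomato+ libraries average 83.2 against 59.9 CPM, and 6W muscle holds the highest group mean, 328 CPM.

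In the heart at P1, TdTomato+ cells held less RNA of endocardial, lymphatic and fibroblast marker genes than TdTomato- cells, and more of the chemokine gene Cxcl12 and of stress-responsive genes. Cxcl12 (chromosome 6, 117168535 to 117181368) rose 2.99-fold (log2 fold change 1.58 ± 0.14, SE, n = 4 pairs). Glul, which encodes glutamine synthetase, rose 2.38-fold, the thromboxane receptor gene Tbxa2r 2.43-fold, Syt7 2.27-fold, the transcription factor gene Tbx2 2.08-fold and the collagen gene Col8a1 by 1.07 on the log2 scale. The cartilage matrix gene Comp (chromosome 8, 70373548 to 70382066) fell by 7.75 on the log2 scale (SE 1.01), Cytl1 by 7.37, Mmrn1 by 5.83, the ephrin receptor gene Epha7 by 5.19 and Nipal4 by 5.16. Plvap, a protein of the diaphragms of fenestrated endothelium, was 8.46-fold lower in TdTomato+ cells (log2 fold change -3.08 ± 0.25).

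Of 12 endocardial genes, 11 fell (12 adjusted over the list alone), among them Npr3, the natriuretic peptide clearance receptor (log2 fold change -4.79 ± 0.56), and Foxc1 (-1.72 ± 0.17). The list as a whole was lower than other genes in the camera test (adjusted p = 8.51e-19, and adjusted p = 0.00922 with an estimated correlation). Lymphatic genes fell in 6 of 11 (7 adjusted over the list alone; camera adjusted p = 6.95e-10, and 0.0192 with an estimated correlation), with Fgl2 at -3.21 ± 0.38. Fibroblast markers fell in 9 of 16 (11 adjusted over the list alone; camera adjusted p = 8.34e-13, and 0.0473 with an estimated correlation), with the matrix genes Postn at -4.85 ± 0.76 and Mfap5 at -1.59 ± 0.27. TdTomato+ library 5 stood apart in these lists. Its mean log2 CPM was 3.56 for fibroblast, 3.44 for endocardial and 1.37 for lymphatic genes, against -0.76 to 0.92, 1.49 to 2.30 and -0.18 to 0.59 in TdTomato+ libraries 2 to 4 and 4.70, 6.06 and 3.85 in its partner. Its pair had equal RNA integrity numbers (8.5 each), where pairs 2, 3 and 4 had 7.5, 7.1 and 3.6 in TdTomato+ against 9.2, 8.0 and 8.4 in TdTomato- libraries. Both Xist and Ddx3y RNA reached 10 CPM in pair 5, where only Xist did in pairs 2, 3 and 4. Without pair 5, 11 of 16 fibroblast, 12 of 12 endocardial and 6 of 11 lymphatic genes fell. In a fit of the P1 heart libraries alone 4 of 13 fibroblast, 11 of 12 endocardial and 5 of 8 lymphatic genes fell, and 1, 10 and 3 of them without the block. Immediate early and heat shock genes, which respond to stress and stimulation within minutes, rose in 19 of 26 (22 adjusted over the list alone), with Btg2 at 0.81 ± 0.09 and Dusp1 at 0.58 ± 0.06 (camera adjusted p = 2.17e-22, and 0.0174 with an estimated correlation). Capillary genes rose in 8 of 18 (12 adjusted over the list alone), including the lipoprotein lipase anchor Gpihbp1 (0.69 ± 0.10) and Rgcc (0.82 ± 0.11). The call of this list was not kept by the estimate (camera adjusted p = 3.18e-08; adjusted p = 0.128 with an estimated correlation). The same held for arterial genes, of which 8 of 22 rose and 1 fell, with Sox17 at 0.80 ± 0.08 (adjusted p = 0.307 with an estimated correlation). It also held for venous genes, of which 5 of 18 fell and 1 rose, with the prostaglandin synthase gene Ptgs1 at -0.93 ± 0.13 (adjusted p = 0.147 with an estimated correlation), and for oxidative phosphorylation genes, of which 11 of 30 rose and 2 fell (adjusted p = 0.307 with an estimated correlation).

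In all, 2294 of 15557 genes differed between the fractions of P1 heart, 1175 higher and 1119 lower in TdTomato+ cells, at a Benjamini-Hochberg adjusted p below 0.05 in edgeR's quasi-likelihood test. Of the called genes that differed at least 2-fold, 44 were higher and 622 lower. Of these 666, 66 had no count in any library of 1 fraction, all with at least a 2-fold difference when 3 counts were allowed there over the group. Without the replicate block 1124 genes were called. A fit of the P1 heart libraries alone called 457 (179 higher and 278 lower), or 300 without the block (79 and 221). Without pair 2, 3 or 4 the count was 1192, 984 or 924, with pair 1 included it was 1339, and with the RNA integrity number as a covariate, added after seeing the data, 739. Of the genes named above, Col8a1 and Tbx2 did not pass without pair 2, 3 or 4 (log2 fold changes 0.74 to 1.13 and 0.78 to 1.18).

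In the lung at P1, TdTomato+ cells had more RNA of capillary and fatty acid uptake genes. The mucosal addressin gene Madcam1 (chromosome 10, 79664574 to 79668536) rose 13.2-fold (log2 fold change 3.72 ± 0.42, SE, n = 5 pairs), and the glycerol channel gene Aqp7 (chromosome 4, 41033074 to 41048136) 11.7-fold (3.55 ± 0.22). Further rises were those of the retinol-binding protein gene Rbp7, 10.6-fold (3.40 ± 0.19), the fatty acid-binding protein gene Fabp4, 9.06-fold (3.18 ± 0.21), the E-selectin gene Sele, 8.51-fold, and the chemokine gene Cxcl1, 5.78-fold. The genes that fell most were the platelet tubulin gene Tubb1 (-3.06 ± 0.76), the glucose transporter gene Slc2a3 (-2.61 ± 0.84) and Pcdhac2 (-1.84 ± 0.45). They were followed by the carbonic anhydrase gene Car4 (-1.72 ± 0.10), the platelet integrin gene Itga2b (-1.64 ± 0.36) and the cannabinoid receptor gene Cnr2 (-1.60 ± 0.39). Pcdhac2 shares exons with the other protocadherin alpha genes, so its value is uncertain.

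Of 18 capillary and fatty acid uptake genes, 12 rose and 4 fell, the same numbers as adjusted over the list alone, and the list was higher in the camera test (adjusted p = 4.14e-30, and 0.00298 with an estimated correlation). Car4 was among the members that fell. Venous genes rose in 8 of 18 and fell in 1, with the neuropilin gene Nrp2 at 0.86 ± 0.14, and immediate early genes rose in 12 of 26, with Zfp36 at 0.80 ± 0.09 and Egr1 at 0.72 ± 0.10. Both list calls were lost with the estimate (adjusted p = 0.152 with an estimated correlation for each). Pan-endothelial genes fell in 8 of 20, with the tight junction gene Cldn5 at -0.90 ± 0.09 and Icam2 at -0.77 ± 0.07 (camera adjusted p = 1.74e-08, but adjusted p = 0.152 with an estimated correlation). The same list passed as higher in P1 heart, where 9 of 20 rose and 2 fell (camera adjusted p = 0.0014; adjusted p = 0.307 with an estimated correlation). It also passed as lower in 6W heart (adjusted p = 0.343 with an estimated correlation) and as higher in 6W muscle (adjusted p = 0.543 with an estimated correlation). Tip cell genes moved both ways, 6 of 20 up and 6 down, with Plaur at -1.03 ± 0.11 and Apln, which encodes the peptide ligand apelin, at -1.05 ± 0.12. Among 15 proposed endothelial stem or progenitor genes, 2 rose and 4 fell, with Ly6a, the Sca-1 gene, at -0.95 ± 0.09 and Cd34 at -0.49 ± 0.06, and the list had no call. Of 17 lung epithelium markers 1 rose, the alveolar type 2 cell gene Lamp3 (1.76 ± 0.50), and 1 fell, Hopx (-0.71 ± 0.14). The list median log2 fold change was 0.71 for fibroblast and 0.86 for pericyte and smooth muscle markers. Mean log2 CPM of fibroblast markers was higher in the TdTomato+ library of pairs 5, 6, 7 and 8 (3.99, 5.65, 6.59 and 5.08 against 3.51, 4.81, 5.06 and 4.61). It was lower in pair 1 (4.14 against 4.56). Erythroid and platelet markers, among them Itga2b, had a list median of -1.51. Their mean log2 CPM was lower in the TdTomato+ library of pairs 1, 5, 6 and 8 (-0.69, -0.65, 0.65 and 0.49 against 1.63, 1.23, 1.87 and 2.66). In pair 7 it was higher (1.93 against 1.69). Only 2 of the 10 measured markers reached 10 CPM in TdTomato- libraries.

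The test called 1545 genes in P1 lung, 763 higher and 782 lower (edgeR quasi-likelihood, Benjamini-Hochberg). Of those at least 2-fold different, 239 were higher and 58 lower. The count was 745 without the replicate block and 890 or 1003 without pair 7 or 8, and the P1 lung libraries alone gave 828, or 173 without the block. With P1 heart pair 1 included in the joint fit it was 152. The mean log2 CPM of the lung epithelium markers was higher in the TdTomato+ library in pair 6 (6.75 against 5.25), pair 7 (8.32 against 6.47) and pair 8 (7.75 against 6.03). It was lower there in pair 1 (4.49 against 5.43) and pair 5 (4.37 against 4.64). With this level as a covariate 916 genes were called. Calls were lost without 1 pair for Slc2a3 (pair 1, 5, 6 or 8; log2 fold change -3.10 to -1.87), Pcdhac2 (any pair; -1.55 or lower), Cnr2 (pair 8; -1.32) and Lamp3 (pair 6, 7 or 8; 1.27 to 1.48).

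In muscle at P6, TdTomato+ cells had more RNA of venous, capillary and antigen presentation genes, and less of lymphatic and arterial genes. Rises were 17.9-fold for the L-selectin ligand gene Glycam1 (log2 fold change 4.16 ± 0.63, SE, n = 5 pairs) and 20.4-fold for Fut7, a fucosyltransferase of selectin ligand synthesis (4.35 ± 0.98). They were 18.6-fold for the ubiquitin-like gene Ubd, 4.11-fold for Madcam1 and 3.94-fold for the transcription factor gene Foxf1. Serpina1e rose 66.3-fold, but it belongs to a cluster of near-identical serpin genes and is uncertain. The solute carrier gene Slc45a3 (chromosome 1, 131962915 to 131982972) fell by 3.04 (SE 0.33), Mmrn1 by 2.81, Fgl2 by 2.02, the hyaluronan receptor gene Lyve1 by 1.78 and the cell polarity gene Pard6g by 1.68 on the log2 scale. Gja5 (chromosome 3, 97032402 to 97053634), which encodes the arterial gap junction protein connexin 40, fell by 1.66 (SE 0.17).

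Lymphatic genes fell in 4 of 11 (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.52e-16, and 0.00303 with an estimated correlation). Arterial genes fell in 5 of 22, or 12 adjusted over the list alone (camera adjusted p = 9.1e-19, and 0.00367 with an estimated correlation). Venous genes rose in 2 of 18, Lrg1 (1.91 ± 0.24) and Plvap (1.04 ± 0.21), and the list as a whole was higher (camera adjusted p = 1.48e-11, and 0.00367 with an estimated correlation). Capillary genes rose in 4 of 18, with Car4 at 0.73 ± 0.10 and the lipase gene Lpl at 0.58 ± 0.08 (camera adjusted p = 9.29e-16, and 0.011 with an estimated correlation). Genes of antigen presentation rose in 3 of 15, or 12 adjusted over the list alone, with the class I genes H2-T23 at 0.55 ± 0.07 and H2-K1 at 0.37 ± 0.07, which have close paralogs (camera adjusted p = 4.96e-17, and 0.00303 with an estimated correlation). The mean log2 CPM of leukocyte markers was higher in the TdTomato+ library in pairs 2 to 5 (0.21, 2.48, 1.90 and 1.15 against -0.62, 0.80, 0.84 and -0.08) and lower in pair 1 (-1.15 against -0.28). Interferon response genes rose in 3 of 30, or 10 adjusted over the list alone, and immediate early genes in 9 of 26, with Nr4a1 at 0.66 ± 0.10 (adjusted p = 0.0115 and 0.011 with an estimated correlation). Tip cell genes fell in 2 of 20, with Apln at -0.59 ± 0.12 (adjusted p = 0.0475 with an estimated correlation). The S phase list was lower (adjusted p = 0.0401 with an estimated correlation) although 0 of its 25 genes passed in edgeR's quasi-likelihood test over all genes. Adjusted over the list alone 2 passed, 4 had an unadjusted p below 0.05, and DESeq2 called 1.

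The test called 154 genes in P6 muscle, 100 higher and 54 lower (edgeR quasi-likelihood, Benjamini-Hochberg), against 1230 at an unadjusted p below 0.05. Without the block 25 genes were called, with P1 heart pair 1 included 7 were called, and the P6 muscle libraries alone gave 471, or 344 without the block. Leaving out pair 1, 2, 3, 4 or 5 left 83, 86, 87, 70 or 71. Fut7 lost its call without any 1 pair (log2 fold change 4.06 to 4.59), and Lyve1 without pair 1, 2, 4 or 5 (-1.87 to -1.58). Plvap lost it without pair 3, 4 or 5 (0.99 to 1.01), Apln without pair 2, 3 or 5 (-0.59 to -0.56) and H2-K1 without pair 4 (0.33).

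In the heart at 6W, TdTomato+ cells had more RNA of pericyte, smooth muscle and fibroblast markers and of venous endothelial genes, and less of arterial genes. The microfibril gene Mfap4 (chromosome 11, 61485444 to 61488704) rose 7.73-fold (log2 fold change 2.95 ± 0.44, SE, n = 5 pairs), the chloride channel gene Ano1 7.67-fold and the matrix gene Postn 6.54-fold. The nitric oxide receptor subunit gene Gucy1a3 rose 6.23-fold, the matrix gene Aspn 5.62-fold and the P-selectin gene Selp by 2.35 on the log2 scale. The falls were smaller: Aif1l by 1.18 (SE 0.23), Gja5 by 1.05 (SE 0.17), the elastic fibre gene Fbln5 by 1.05, the lipoxygenase gene Alox12 by 0.87, Apln by 0.82 and the kinase gene Cdk19 by 0.74 on the log2 scale.

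Of 16 pericyte and smooth muscle markers, 6 rose, or 16 adjusted over the list alone, including the smooth muscle kinase gene Mylk (1.01 ± 0.12) and Ndufa4l2 (2.35 ± 0.45; camera adjusted p = 2.46e-29, and 0.00419 with an estimated correlation). This rise differed between pairs. The mean log2 CPM of the markers was 5.78, 6.54 and 5.83 in the TdTomato+ libraries of pairs 1, 2 and 4 against 3.71, 3.20 and 1.99 in their partners. It was 3.90 and 5.29 in those of pairs 5 and 6 against 4.14 and 4.25. The RNA integrity number was 7.4 to 7.7 in TdTomato+ against 9.0 to 9.2 in TdTomato- libraries of pairs 1, 2 and 4, 9.4 against 9.0 in pair 5 and 9.3 against 9.7 in pair 6. Pairs 5 and 6 came from the other sequencing run, and 1 of their labels names muscle. Their mean log2 CPM was 3.27 to 4.28 for cardiomyocyte and -1.77 to -1.17 for skeletal muscle markers, where 6W muscle libraries held -1.75 to -0.72 and 0.67 to 2.81. Cardiomyocyte markers stood at 1.14 to 1.87 in pairs 1, 2 and 4, and mitochondrial reads made up 0.81 to 1.40% there and 2.93 to 5.01% in pairs 5 and 6. Fibroblast markers rose in 3 of 16, or 7 adjusted over the list alone, with Fbln1 at 2.36 ± 0.52 (camera adjusted p = 4.7e-15, and 0.0211 with an estimated correlation). This rise also lay mostly in pairs 1, 2 and 4. Their mean log2 CPM of fibroblast markers was 4.73, 5.64 and 4.16 in TdTomato+ against 2.32, 3.05 and 2.15 in TdTomato- libraries. In pairs 5 and 6 it was 3.64 and 3.93 against 3.52 and 3.18. Venous genes rose in 7 of 18, or 11 adjusted over the list alone, with the vein-determining transcription factor gene Nr2f2 at 1.00 ± 0.17 and Lrg1 at 1.39 ± 0.24 (camera adjusted p = 7.05e-16, and 0.00131 with an estimated correlation). Arterial genes fell in 4 of 22, or 12 adjusted over the list alone (camera adjusted p = 2.74e-14, and 0.0138 with an estimated correlation). Mitotic G2/M genes fell in 2 of 30, or 10 adjusted over the list alone, with Birc5 at -1.44 ± 0.28 and Kif20a at -1.56 ± 0.34 (camera adjusted p = 4.7e-15, and 0.0138 with an estimated correlation). Only 2 of the 30 reached 10 CPM in TdTomato- libraries, so most of this list lay near the floor. Procr, a proposed progenitor marker, rose (0.57 ± 0.13), as did the immediate early gene Myc (1.35 ± 0.16).

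**Figure D2:**
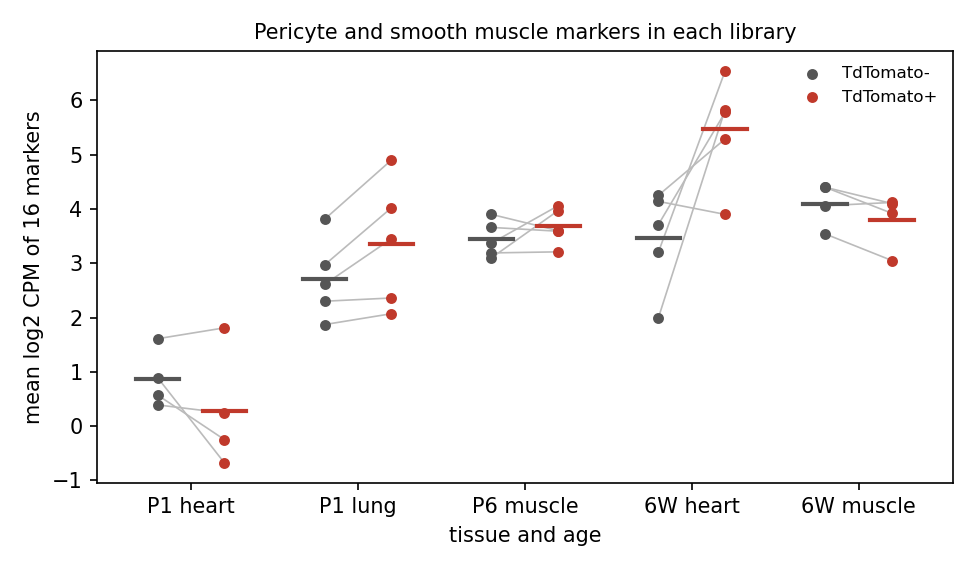
Mean log2 CPM of the 16 pericyte and smooth muscle markers in each of the 46 libraries, by tissue and age, with matched pairs joined by lines and group means as bars. In 6W heart the TdTomato+ libraries of pairs 1, 2 and 4 stand at 5.78, 6.54 and 5.83, against 3.71, 3.20 and 1.99 in their partners.

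The test called 140 genes in 6W heart, 92 higher and 48 lower (edgeR quasi-likelihood, Benjamini-Hochberg), against 1790 at an unadjusted p below 0.05. Without the replicate block 87 genes were called, with P1 heart pair 1 included 1 was called, and the 6W heart libraries alone gave 27, or 7 without the block. More were called without 6W heart pairs 5 and 6 (367) and by DESeq2 on the same design (552). Without pair 1, 2, 4 or 5 the count was 36, 24, 38 or 283. Under 3 alternatives added after seeing the data, edgeR called 0 genes with pairs 1, 2 and 4 all left out (521 at an unadjusted p below 0.05), 0 with the pericyte marker level as a covariate (494) and 25 with the RNA integrity number as a covariate. Of the called genes named above, 15 lost their call when 1 pair was left out. Ano1, Gucy1a3, Aspn, Ndufa4l2 and Fbln1 lost it without pair 1, 2 or 4 (log2 fold changes 1.86 to 2.73), and Postn without those or pair 6 (2.42 to 2.87). Selp lost it without pair 1 or 2 (2.06 and 2.08), Nr2f2 and Lrg1 without pair 2 (0.77 and 1.24), and Procr without pair 2, 4, 5 or 6 (0.48 to 0.62). Among genes that fell, Cdk19 and Kif20a lost theirs without pair 1, 2, 4 or 6 (-0.80 to -0.65 and -1.55 to -1.17), and Aif1l, Fbln5 and Birc5 without pair 1 or 4 (-1.16 to -0.91, -1.03 to -0.89 and -1.32 to -1.27).

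In muscle at 6W, arterial genes were lower and venous genes higher in TdTomato+ cells. Gja5 was 5.94-fold lower (log2 fold change -2.57 ± 0.20, SE, n = 4 pairs), Gja4, which encodes connexin 37 of arterial endothelium, 3.94-fold lower (-1.98 ± 0.17), the oestrogen receptor gene Gper1 6.28-fold, Tmem178 4.76-fold, Col8a1 3.94-fold and Aif1l 3.66-fold lower. Selp rose 4.06-fold (2.02 ± 0.43), Lrg1 2.99-fold, Plvap (chromosome 8, 71497753 to 71511769) 2.95-fold (1.56 ± 0.23), the leukotriene receptor gene Cysltr1 and the amino acid transporter gene Slc7a5 2.77-fold each, and the collagen gene Col13a1 2.71-fold.

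Venous genes rose in 14 of 18 (16 adjusted over the list alone), among them Ptgs1 (0.91 ± 0.13) and the prostaglandin transporter gene Slco2a1 (1.26 ± 0.18; camera adjusted p = 9.06e-27, and 7.02e-05 with an estimated correlation). Arterial genes fell in 10 of 22 and rose in 1 (12 and 1 adjusted over the list alone), with the Notch target Hey1 at -1.28 ± 0.10 (camera adjusted p = 1.04e-24, and 0.00197 with an estimated correlation). RNA integrity was lower in the TdTomato+ library in 4 of 4 pairs, and with its number as a covariate, added after seeing the data, the arterial list had adjusted p = 0.0795 and the venous list adjusted p = 0.00561 with an estimated correlation. Subunits of the oxidative phosphorylation complexes fell in 13 of 30, or 21 adjusted over the list alone, with Ndufs4 at -0.65 ± 0.10 and Ndufb8 at -0.61 ± 0.10. The list's call was lost with the estimate (camera adjusted p = 1.89e-16; adjusted p = 0.0951 with an estimated correlation). G2/M genes fell in 6 of 30, with Ube2c at -1.88 ± 0.35, and interferon response genes in 4 of 30, with Isg15 at -0.77 ± 0.14 (adjusted p = 0.145 and 0.141 with an estimated correlation). Only 1 of the 30 G2/M genes reached 10 CPM in TdTomato- libraries, so most of that list lay near the floor. Capillary genes fell in 3 of 18, with Rbp7 at -1.29 ± 0.17 (adjusted p = 0.268 with an estimated correlation), where Rbp7 had risen in P1 lung. Skeletal muscle markers fell in 5 of 19, with the actin gene Acta1 at -1.58 ± 0.33 (adjusted p = 0.125 with an estimated correlation). Of 8 measured glia and neuron markers 1 fell, Stmn2 (-1.61 ± 0.15), which also stands in the arterial list, and the list was lower (camera adjusted p = 4.95e-05, and 0.0282 with an estimated correlation). The cardiac transcription factor gene Gata4 had 0 counts in the TdTomato+ libraries and was at least 14.8-fold lower there against a floor of 3 counts over the group.

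The test called 824 genes in 6W muscle, 273 higher and 551 lower (edgeR quasi-likelihood, Benjamini-Hochberg). The count was 255 without the replicate block, 78 in an unblocked fit of the 6W muscle libraries alone, 8 with P1 heart pair 1 included, and 447, 403 or 242 without pair 2, 3 or 4. A fit of the 6W muscle libraries alone with the block called 1184, and DESeq2 on the same design called 1412. Calls were lost for Gper1 without pair 3 (log2 fold change -2.45), Selp without pair 4 (1.82), Cysltr1 without pair 2, 3 or 4 (1.33 or more), Slc7a5 without pair 3 or 4 (1.14 to 1.46), and Gata4 without pair 2, 4 or 5.

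**Figure D3:**
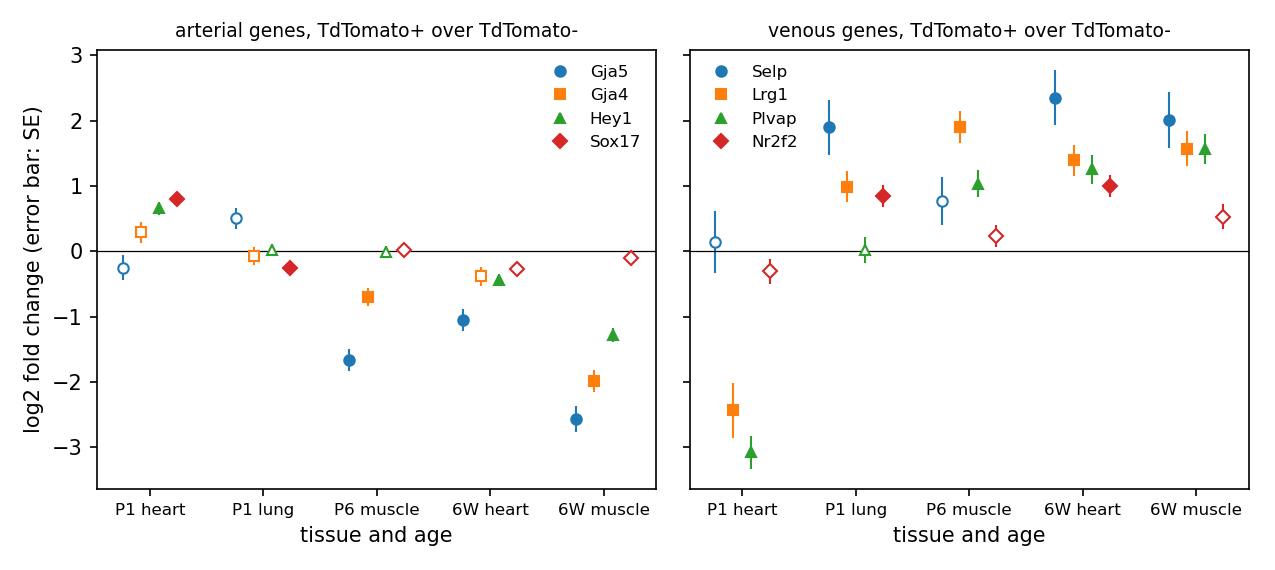
Log2 fold change of TdTomato+ over TdTomato- cells for arterial and venous genes in the 5 combinations of tissue and age, with SE from the edgeR fit; filled points passed the test at an adjusted p below 0.05. Open points did not pass. Gja5 stands at -2.57 in 6W muscle, Selp at 2.35 in 6W heart and Plvap at -3.08 in P1 heart.

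Averaged over the 5 combinations, TdTomato+ cells had more RNA of venous genes, capillary genes and immediate early genes, and less of arterial, lymphatic and cell cycle genes. These averages did not hold in every combination. The list median log2 fold change was -0.14 for venous genes in P1 heart, and 0.14 and 0.16 for arterial genes in P1 heart and P1 lung. For capillary genes it was 1.36 in P1 lung but -0.10 in 6W heart and -0.28 in 6W muscle. For lymphatic genes it was -3.21 in P1 heart and -1.63 in P6 muscle, but 0.01 in P1 lung and -0.06 in 6W muscle. Among genes with the same sign in all 5, the largest mean rises were in the chemokine scavenger gene Ackr1 (log2 fold change 1.95 ± 0.40, SE), Selp (1.44 ± 0.19), Fmod (1.40 ± 0.31) and Notch3 (1.12 ± 0.29). Next came the cytokine receptor genes Csf2rb (1.06 ± 0.14) and Csf2rb2 (1.04 ± 0.23), the class II gene H2-Eb1 (1.03 ± 0.25), Lrp1, Rcan2 and Rasd1. Csf2rb and Csf2rb2 are near-identical copies, so their values are uncertain. The largest mean falls were in Edil3 (-3.13 ± 0.46), Cytl1 (-2.49 ± 0.38), Lyve1 (-1.71 ± 0.22), the mitotic checkpoint gene Bub1 (-1.71 ± 0.39), Slc45a3 (-1.60 ± 0.15), Enpp6 (-1.42 ± 0.25), Iqgap3 (-1.37 ± 0.16), Fignl1, Melk and Cep55. Bub1 had 0 counts in the TdTomato+ libraries of 6W muscle, so the size and rank of its mean fall are uncertain.

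Venous genes rose on average in 13 of 18, with Sele at 1.89 ± 0.26 (adjusted p = 0.000371 with an estimated correlation). Arterial genes fell in 12 of 22 and rose in 1, with Gja5 at -1.0 ± 0.08 (adjusted p = 0.0231 with an estimated correlation). Immediate early genes rose in 22 of 26, with Zfp36 at 0.58 ± 0.04 and Ier3 at 0.51 ± 0.05 (camera adjusted p = 8.47e-53, and 0.000371 with an estimated correlation). Capillary genes rose in 12 of 18 and fell in 1, with Aqp7 at 0.81 ± 0.08, and lymphatic genes fell in 5 of 11, with Mmrn1 at -1.92 ± 0.21 (adjusted p = 0.00505 with an estimated correlation for each). G2/M genes fell in 15 of 30, with Birc5 at -0.65 ± 0.11 and Ccnb2 at -0.73 ± 0.13 (adjusted p = 0.0155 with an estimated correlation). All 30 reached 10 CPM in TdTomato- libraries of P1 heart, P1 lung and P6 muscle, but only 2 in 6W heart and 1 in 6W muscle. S phase genes fell in 7 of 25, with Rrm1 at -0.38 ± 0.08 (adjusted p = 0.0381 with an estimated correlation). Apln fell by 0.58 (SE 0.06), the fibronectin gene Fn1 by 0.73 (SE 0.07) and Gja4 by 0.57 (SE 0.07). The test called 1323 genes on the mean effect, 689 higher and 634 lower (edgeR quasi-likelihood, Benjamini-Hochberg). Without the replicate block 382 genes were called, with P1 heart pair 1 included 140, and without P1 heart pair 5 the count was 2197. With the RNA integrity number as a covariate, added after seeing the data, it was 88. Of 33 called genes named for the mean, Fmod lost its call without P1 heart pair 5 (1.26), Notch3 and H2-Eb1 without P1 heart pair 4 (0.88 each) and Bub1 without 6W muscle pair 3 (-1.46). Melk and Cep55 lost theirs in 16 and 14 of the 23 fits that leave out 1 pair (-0.84 to -0.67 and -0.83 to -0.65).

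The lists that follow had no camera call in the named combinations, or one that was lost with an estimated correlation. The proposed stem or progenitor list and the other ABC transporters had no camera call in any of the 5 combinations or the mean, with at most 4 of 15 and 3 of 25 members moving in 1 direction. Notch genes passed the camera test as lower in P6 muscle (adjusted p = 0.0484; adjusted p = 0.164 with an estimated correlation), where 1 of 20 fell. In P1 heart 8 of 20 rose and 2 fell, with a median log2 fold change of 0.33 and a mean of -0.25, and the list did not pass (camera adjusted p = 0.0707). The lists of aryl hydrocarbon receptor and Nrf2 targets, TGF-beta and mesenchymal transition, and shear stress and nitric oxide passed in no combination. Glycolysis and hypoxia genes passed as higher in P6 muscle and in the mean (adjusted p = 0.0957 and 0.173 with an estimated correlation). Wnt and blood-brain barrier genes were lower in P1 heart and higher in both muscle ages (adjusted p = 0.147, 0.072 and 0.136 with an estimated correlation). Of the other cell types, cardiomyocyte markers passed as lower in P1 heart (adjusted p = 0.307 with an estimated correlation), leukocyte markers as higher in P6 muscle (adjusted p = 0.15 with an estimated correlation) and lung epithelium markers as higher in 6W heart (adjusted p = 0.383 with an estimated correlation). Glia and neuron markers passed as lower in P6 muscle and in the mean (adjusted p = 0.0992 and 0.0943 with an estimated correlation), and pericyte markers as higher in the mean (adjusted p = 0.339 with an estimated correlation). In P1 lung erythroid and platelet markers passed as lower and mesothelium markers as higher (adjusted p = 0.297 for each with an estimated correlation). Of 180 camera tests on the 30 lists, 68 passed at an adjusted p below 0.05, 29 of these also with an estimated correlation, and 63 passed without the replicate block.

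Called genes were compared between pairs of combinations, which have no library in common, with the product of the list sizes over the genes tested as the number that independent lists would share. Over 20 entries of 10 pairs and 2 directions, the shared genes exceeded it in 16 for genes called the same way and in 16 for genes called in opposite ways. Across genes, which are not independent replicates, the log2 fold changes of 2 combinations had correlations of -0.15 to 0.13. P1 heart and P1 lung shared 174 genes higher in TdTomato+ cells against 57.6, while 130 genes higher in P1 heart were lower in P1 lung against 59.1. Of the genes lower in P1 lung, 26 were higher in P6 muscle against 5.03 and 7 lower there against 2.71. P6 and 6W muscle shared 14 higher and 19 lower genes against 1.75 and 1.91, and 6W heart and 6W muscle 17 higher and 14 lower genes against 1.61 and 1.70. Between P1 and 6W heart, 3 genes were higher in both against 6.95, and 28 of the genes lower at P1 were higher at 6W against 6.62. Of the 15557 genes, 2 were called in all 5 combinations, 13 in 4, 125 in 3, 691 in 2 and 3138 in 1.

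In the heart, the difference between the fractions changed with age for the matrix gene Postn and for others. Postn was 28.8-fold lower in TdTomato+ cells at P1 and 6.54-fold higher at 6W, a difference of log2 fold changes of 7.56 ± 0.97 (SE). Comp (7.50 ± 1.19), Cytl1 (7.08 ± 1.34), the superoxide dismutase gene Sod3 (6.96 ± 0.88) and the collagen gene Col3a1 (6.59 ± 1.20) moved the same way. Postn and Col3a1 stand in the fibroblast list, whose median log2 fold change was -2.59 at P1 and 1.61 at 6W. The rise of that list at 6W lay mostly in pairs 1, 2 and 4. Whether fibroblast RNA gives these age differences was not tested. The fraction difference was lower at 6W for Aim1 (-3.30 ± 0.53), Iqgap3 (-2.60 ± 0.52), Fez1 (-2.34 ± 0.38), Aif1l (-2.02 ± 0.34) and Cxcl12 (-1.90 ± 0.19). The edgeR quasi-likelihood test of this age difference called 1262 genes (Benjamini-Hochberg). Without the replicate block 670 genes were called, with P1 heart pair 1 included 536, and without P1 heart pair 3 or 5 or 6W heart pair 2 the count was 749, 2040 or 812. With 6W heart pairs 1, 2 and 4 left out it was 203, and with the pericyte marker level as a covariate 61, both added after seeing the data.

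In muscle the fraction difference was lower at 6W than at P6 for Glycam1, Ubd and Madcam1. The difference of the log2 fold changes was -5.42 ± 1.00 (SE) for Glycam1, -5.04 ± 0.56 for Ubd and -2.95 ± 0.58 for Madcam1, and -2.90 ± 0.49 for the mitotic gene Fam64a and -2.14 ± 0.55 for Iqgap3. Genes whose fraction difference was higher at 6W were Mmrn1 (2.92 ± 0.58), Slc45a3 (2.83 ± 0.47), Fgl2 (2.35 ± 0.44), Gprin3 (1.82 ± 0.44) and Pard6g (1.79 ± 0.32). This test called 248 genes, 70 higher and 178 lower (edgeR quasi-likelihood, Benjamini-Hochberg), against 3 without the replicate block and 2 with P1 heart pair 1 included. Without P6 muscle pair 1, 2 or 5 the count was 148, 143 or 116, and without 6W muscle pair 2, 3 or 4 it was 142, 118 or 50. Glycam1, Fam64a, Mmrn1 and Fgl2 lost their calls without 6W muscle pair 4 (-4.90, -3.12, 2.42 and 2.12), and Madcam1 without 6W muscle pair 2 (-2.56). Iqgap3 lost it without any 1 of the 9 pairs (-2.33 to -1.94) and Gprin3 without any but P6 muscle pair 5 (1.69 to 2.03). A test that the 5 fraction differences are equal, over all tissues and ages, called 2641 genes (edgeR quasi-likelihood, Benjamini-Hochberg), 1264 without the replicate block and 448 with P1 heart pair 1 included.

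Age was compared within each fraction, in muscle between libraries of different sequencing runs. In heart TdTomato- cells at 6W against P1, the xanthine oxidoreductase gene Xdh rose 437-fold (log2 fold change 8.77 ± 0.52, SE, n = 5 and 4), the flavin monooxygenase gene Fmo2 326-fold and Gda, which encodes guanine deaminase, 132-fold. The cytochrome gene Cyp1a1 rose 263-fold, and Pbld1 and Slc1a1 rose from P1 libraries that held only 2 counts of Pbld1 and 2 of Slc1a1 in all, a ratio of 1890-fold (95% counting interval 522 to 15600) and 983-fold (272 to 8120). The fetal growth genes H19, an imprinted RNA, and Mdk fell by 7.98 and 6.97, Add2 by 8.23, the X-linked gene Capn6 by 7.66, and the DNA repair and replication genes Neil3 and Pole by 6.59 and 6.16 on the log2 scale.

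In heart TdTomato+ cells Fmo2 rose by 9.52 ± 0.44 on the log2 scale (n = 5 and 4). The olfactory receptor gene Olfr78 had 0 counts at P1 and was at least 628-fold higher at 6W against a floor of 3 counts over the group. Pbld1 had 1 count at P1 (ratio 2870-fold, 95% counting interval 514 to 113000), Mrvi1 2 counts (1000-fold, 277 to 8290), Cyp1a1 3 counts (1590-fold, 544 to 7720) and Slc1a1 3 counts (682-fold, 233 to 3310). The mitotic genes Kif11 (-7.63 ± 0.92), Cep55 (-7.32 ± 0.73), Birc5 (-7.32 ± 0.50) and Iqgap3 (-7.00 ± 0.66), the polymerase gene Pole (-7.40 ± 0.82) and Arxes1 (-7.20 ± 0.72) fell.

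In muscle TdTomato- cells at 6W against P6, the cytochrome gene Cyp1a1 rose by 10.92 ± 1.15 on the log2 scale (n = 4 and 5), and the class II genes H2-Aa and H2-Ab1 by 7.35 ± 1.04 and 6.75 ± 0.98, or by 3.59 and 2.98 with 6W libraries 3 and 4 left out. Other rises were those of Fgf9 by 7.24 ± 0.92, Fmo2 by 6.75 ± 0.24 and Xdh by 6.61 ± 0.43. The replication gene Dtl fell by 8.34, H19 by 8.05, the prion-like gene Prnd by 7.69, Bub1 by 6.13, Ncapg by 5.90 and Nuf2 by 5.87.

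In muscle TdTomato+ cells Cyp1a1 (8.62 ± 0.96), Fgf9 (274-fold), the transcription factor gene Klf15 (7.49 ± 0.83), Fmo2 (7.15 ± 0.34) and Xdh (6.15 ± 0.65) rose. At 6W the TdTomato+ libraries held 0 counts of Bpifa2 and of Bub1, which were at least 5990-fold and 574-fold lower there against the floor of 3 counts over the group; Bpifa2 lost its call with 6W libraries 3 and 4 left out. H19 (-8.88 ± 0.99), Prnd (-8.47 ± 0.63), Ncapg (-7.31 ± 0.62) and Fam64a (-7.23 ± 0.74) fell.

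All 25 S phase and all 30 G2/M genes were lower at 6W than in the neonate in each fraction of heart and muscle. The camera adjusted p for S phase with an estimated correlation was 0.0421 and 0.0661 in TdTomato- cells of heart and muscle and 0.00529 and 0.00776 in TdTomato+ cells. For G2/M it was 0.151 and 0.0661 in TdTomato- cells of heart and muscle and 0.0353 and 0.00776 in TdTomato+ cells. Antigen presentation genes rose in 15 of 15 in both muscle fractions, and in 13 of 15 TdTomato- and 9 of 15 TdTomato+ heart cells. In 6W muscle their mean log2 CPM was 9.06 and 8.93 in TdTomato+ libraries 3 and 4 (8.86 and 8.72 in their partners) but 6.03 and 4.60 in libraries 2 and 5 (6.18 and 5.40), and the TdTomato+ libraries of P6 muscle held 4.06 to 5.33. With 6W libraries 3 and 4 left out, an alternative added after seeing the data, 12 of 15 rose in TdTomato- and 7 of 15 in TdTomato+ muscle cells. Interferon response genes rose in 26 and 28 of 29 in TdTomato- cells of heart and muscle and in 22 and 27 of 29 in TdTomato+ cells. Neither list kept its call with an estimated correlation (adjusted p = 0.279 and 0.279 in TdTomato- heart, 0.177 and 0.101 in TdTomato- muscle, 0.31 and 0.31 in TdTomato+ heart, and 0.22 and 0.22 in TdTomato+ muscle). Capillary genes rose in 17 of 18 in TdTomato- heart (adjusted p = 0.00744 with an estimated correlation), where 11 of 12 endocardial genes fell (adjusted p = 0.0421 with an estimated correlation). Tip cell genes fell in 10 to 12 of 20, with Apln down by 3.05 and 3.96 in TdTomato- and TdTomato+ heart and by 5.52 and 5.46 in muscle. Abcb1a, the P-glycoprotein gene, rose in TdTomato- heart and muscle by 2.84 and 2.53 and in TdTomato+ heart and muscle by 2.27 and 2.79 on the log2 scale. Ly6a rose by 3.40 and 3.26 in TdTomato- heart and muscle and by 2.81 in TdTomato+ muscle.

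The age comparisons called 7278 genes in TdTomato- heart (3538 higher and 3740 lower at 6W), 6418 in TdTomato+ heart (3224 and 3194), 6254 in TdTomato- muscle (3097 and 3157) and 5074 in TdTomato+ muscle (2442 and 2632), at a Benjamini-Hochberg adjusted p below 0.05 in edgeR's quasi-likelihood test. In muscle the 2 ages were sequenced in different runs, so run and age cannot be told apart. In heart, 6W pairs 1, 2 and 4 shared a run with the P1 libraries, and leaving out pairs 5 and 6 of the other run left 6606 genes in TdTomato- and 5520 in TdTomato+ cells. With P1 heart library 1 included, the count in TdTomato+ heart was 3534. Sex-linked RNA was not balanced over age either. All P6 muscle libraries held Ddx3y RNA, where 6W muscle pair 5 held Xist RNA. P1 heart pairs 2, 3 and 4 held Xist RNA and pair 5 both. In 6W heart, pairs 1, 2 and 6 held Ddx3y RNA and pairs 4 and 5 Xist RNA.

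In the authors' deposited table, 3146 genes had a false discovery rate below 0.05 between the fractions of P1 heart, 191 in P1 lung, 15 in P6 muscle, 69 in 6W heart and 33 in 6W muscle. Of these, 1316, 172, 12, 39 and 30 were also called in the same direction in the paired fit. The P1 heart fold changes of the authors' deposited table matched, within 0.1 for 99.9% of genes, an unpaired fit of all 48 libraries that keeps pair 1, and for 12.3% a fit without it. Abcg2 stands there at a log2 fold change of 1.66 in P1 heart, against 0.06 in the unpaired fit without pair 1.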

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

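Among the tests below, those of few starting molecules for genes under 20 CPM by total count and of other heart cells in P1 heart, of pericyte RNA and of preparation in 6W heart, and of sequencing run for arterial and venous genes were chosen after the result was seen, as were the within-pair differences in P1 heart. The RNA integrity number as a covariate was an alternative added after seeing the data, with its tests set before their results were known.

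Of 622 and 44 called genes at least 2-fold lower and higher in P1 heart TdTomato+ cells, loss from few starting molecules is argued against for the 153 lower genes at 20 CPM by total count or more in TdTomato- cells, since at most 0.171% of 5265 genes abundant in every other library lay 5-fold below the TdTomato- median in libraries 2 to 5 (48.1% in the failed library of pair 1); it stays open for the 327 at 2 to 20 CPM and the 142 under 2 CPM, where at most 4.77% of 1803 and 25.7% of 230 such genes lay 5-fold below and few or none 5-fold above. Lower RNA integrity is not settled by the covariate, 1 slope over all 46 libraries. With it the median log2 fold change of the 622 genes was -3.13 against -3.15 (bootstrap interval over genes -3.42 to -2.84). These genes were chosen from the same libraries, and an interval over genes does not measure the spread between pairs. Of them 319 were still called lower, while their median SE grew from 0.72 to 0.85. Their median within-pair difference was -1.86 in pair 5, whose libraries had equal integrity numbers, against -2.50, -2.89 and -2.99 in pairs 2, 3 and 4. In that 1 pair the fall was smaller but present without an integrity difference. RNA of other heart cells of every kind in the TdTomato- libraries stays open: 4 of 4 list medians (cardiomyocyte -0.73, leukocyte 0.50, erythroid and platelet 0.00, pericyte -0.20, or 0.95 for leukocyte and 0.09 for erythroid and platelet genes with empty groups at their bound) stood more than 1 above the fibroblast median of -2.59, but only 2 of 18, 0 of 20, 1 of 10 and 3 of 16 of their markers reached 10 CPM scaled by TMM in TdTomato- libraries (4 of 16 for pericyte markers by total count), too near the floor to decide. RNA of fibroblasts alone is a further candidate source, with Postn at 231 CPM there against 17.7, Col1a2 at 102 against 18.4 and Dcn at 142 against 14.2, although the sort on CD31 should remove such cells, 12 of the 16 markers reached 10 CPM in TdTomato- libraries, and the abundant transcript of Col1a1 did not pass the test (log2 fold change -2.21 ± 1.07). A difference in the kind of endothelial cell between the fractions, such as fewer endocardial cells among TdTomato+ cells, also stays open and was not tested.

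In 6W heart, 16 of 16 pericyte and smooth muscle markers were higher in the TdTomato+ library of each of pairs 1, 2 and 4, and 5 of 16 in both of pairs 5 and 6; this rise is the pattern itself and does not test its source, so RNA from pericytes and smooth muscle cells stays open as a candidate source. Their highest levels were 352.9 against 73.8 CPM for Acta2, 169.1 against 42.7 for Rgs5 and 146.4 against 32.4 for Myh11; the sort on CD31 should remove such cells, 9 of the 16 markers reached 10 CPM in TdTomato- libraries, and 3 stand in another list. Lower RNA integrity stays open, because the integrity gap lay mainly in pairs 1, 2 and 4, which also carry most of the rise. With the integrity number as a covariate, 1 slope over all 46 libraries, the list median was 1.60 against 2.12. Its bootstrap interval (1.30 to 1.78) is over markers and does not measure the spread between pairs. The camera test still passed (adjusted p = 2.82e-24, and adjusted p = 0.00733 with an estimated correlation). Only 1 marker was called against 6 as the folds shrank (median SE 0.53 against 0.57), so a part or all of the rise may follow integrity within 6W heart. Across combinations the list median did not grow with the integrity gap. It was -0.39 in 6W muscle (mean integrity difference -2.12) and -0.20 in P1 heart (-1.85). In P1 lung it was 0.86 (-0.78), in P6 muscle 0.24 (-0.34) and in 6W heart 2.12 (-0.92). Lower integrity therefore did not go with a rise of these markers in 6W muscle, where 11 of 16 reached 10 CPM in TdTomato- libraries. Preparation on another day or run cannot be told apart from another difference between these pairs, because the median within-pair difference was 3.38 in pairs 1, 2 and 4 of one run and 0.51 in pairs 5 and 6 of the other, no pair was sequenced in both, and pairs 5 and 6 also held more cardiomyocyte marker RNA (mean log2 CPM 3.27 to 4.28 against 1.14 to 1.87) and more mitochondrial reads (2.93 to 5.01% against 0.81 to 1.40%). A difference between the fractions, such as more mural cell RNA beside Abcg2-expressing endothelium at this age, stays open as a hypothesis that was not tested.

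Arterial genes were lower and venous genes higher in TdTomato+ cells of muscle and 6W heart. Both libraries of every pair were sequenced in the same run, so a run difference drops out within pairs and comparing the runs could not test it. The venous list median exceeded the arterial one by 0.63 in P6 muscle and 1.35 in 6W heart pairs 1, 2 and 4 of one run. It did so by 1.35 in 6W muscle and 0.57 in 6W heart pairs 5 and 6 of the other. These sets were picked for the pattern. Venous and arterial list medians were -0.14 and 0.14 in P1 heart and 0.42 and 0.16 in P1 lung. Lower RNA integrity of the TdTomato+ libraries cannot be told apart from the fraction in 6W muscle, where it was lower in 4 of 4 pairs. With the integrity number as a covariate the difference there was 1.18 against 1.35 (bootstrap interval over list members 0.77 to 2.14). The camera test with an estimated correlation then gave adjusted p = 0.00561 for venous and adjusted p = 0.0795 for arterial genes. At the preset correlation camera gave adjusted p = 1e-09 for arterial and 3.54e-15 for venous genes. A larger venous share among TdTomato+ endothelial cells of these tissues may explain the pattern and was not tested.

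The reporter effect differed among the 5 combinations for 2641 genes, between the ages of heart for 1262 and between the ages of muscle for 248, by the test of the difference itself (edgeR quasi-likelihood, Benjamini-Hochberg). In heart the log2 fold change at 6W minus that at P1 was 7.56 for Postn, 7.50 for Comp, 7.08 for Cytl1, 6.96 for Sod3, 6.59 for Col3a1, -3.30 for Aim1, -2.60 for Iqgap3, -2.34 for Fez1, -2.02 for Aif1l and -1.90 for Cxcl12. Of these genes, Postn and Col3a1 stand in the fibroblast list. In muscle the difference was 2.92 for Mmrn1, 2.83 for Slc45a3, 2.35 for Fgl2, 1.82 for Gprin3, 1.79 for Pard6g, -5.42 for Glycam1, -5.04 for Ubd, -2.95 for Madcam1, -2.90 for Fam64a and -2.14 for Iqgap3.

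Single libraries stood apart from their group in 3 of 50 combinations of 5 measures and 10 groups, where chance alone singles out about 1 in 20 groups. Abcg2 was 53.8 CPM in P1 lung TdTomato- library 7, with the nearest library of its group at 60.3. Mitochondrial reads made up 0.74% in P1 heart TdTomato+ library 4, with the nearest at 0.65%. The RNA integrity number was 9.7 in 6W heart TdTomato- library 6, with the nearest at 9.2. In the failed P1 heart TdTomato+ library 1, which enters only the alternatives that include it and the unpaired fit of all 48 libraries, Abcg2 stood at 900 CPM by total count against 183 in its partner, and the library held a count for 8631 genes, where the other 47 libraries held one for at least 13048.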

How the results depend on the processing

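Covariates for RNA integrity and for marker levels, and the fits without 6W heart pairs 1, 2 and 4 or 6W muscle libraries 3 and 4, were chosen after seeing the data. The median-ratio scaling and the fit with no filter on low counts moved no count of called genes by over 1.5 times, and no scaling moved the share of higher calls by over 10 percentage points. Of 4413 values of 243 named gene results under the alternatives, 3847 kept their side of the threshold, 565 lost their call, 1 gained one and 0 reversed. Direction was compared only where the main fit or the alternative called the gene. Calls were lost for 70 of 184 without the replicate block, 110 of 184 with P1 heart pair 1 included, 53 with the integrity number, 42 with the pericyte level and 4 of 243 in DESeq2. For the counts below the cause was not tested.

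Without the replicate block, which ignores the pairing, counts of called genes were 1124 in P1 heart (2294 with the block), 745 in P1 lung (1545), 25 in P6 muscle (154), 87 in 6W heart (140), 255 in 6W muscle (824), 382 for the mean effect (1323), 1264 for the test of equal effects (2641), 670 for the age difference in heart (1262) and 3 for that in muscle (248). It changed the camera calls little, 63 against 68 list tests. With an estimated correlation 29 passed. With P1 heart pair 1 included the counts were, in the same order, 1339, 152, 7, 1, 8, 140, 448, 536 and 2, and 3534 for age in heart TdTomato+ cells (6418); the median log2 fold change of all genes was then -0.592 in P1 heart (-0.04 without the pair), 0.553 for the age difference in heart (0.00) and 0.122 for age in heart TdTomato+ cells (0.03). DESeq2 called more: 317 in P6 muscle, 552 in 6W heart, 1412 in 6W muscle, 2226 for the mean, 4117 for equal effects, 2074 and 745 for the age differences in heart and muscle. Fits of 1 comparison alone called 457, 828, 471 and 27 genes with the block in P1 heart, P1 lung, P6 muscle and 6W heart, and 300, 173, 344, 7 and 78 without it in these and 6W muscle. With the replicate number as a block over both ages, age in heart TdTomato+ cells had 3193.

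Without 6W heart pairs 5 and 6, 367 genes were called in 6W heart. With the RNA integrity number as a covariate 739 were called in P1 heart, 25 in 6W heart and 88 for the mean, and with the lung epithelium level 916 in P1 lung. With the pericyte level edgeR called 0 genes in 6W heart (494 at an unadjusted p below 0.05), 748 for the mean and 61 for the age difference in heart. Without 6W heart pairs 1, 2 and 4 it called 0 in 6W heart (521 at an unadjusted p below 0.05) and 203 for the age difference in heart; DESeq2 was not run on these. CPM by total count put Abcg2 at 125 in P1 heart TdTomato- cells (112) and at 121 in TdTomato+ cells (117), which turns the direction, 177 in 6W heart TdTomato- cells (189) and 63.7 in P1 lung TdTomato- cells (59.9).

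Leaving out each pair in turn gave 924 (without pair 4) to 3350 (pair 5) genes in P1 heart, 890 (pair 7) to 1663 (pair 5) in P1 lung, 70 (pair 4) to 87 (pair 3) in P6 muscle, 24 (pair 2) to 283 (pair 5) in 6W heart and 242 (pair 4) to 633 (pair 5) in 6W muscle. The range was 920 (6W muscle pair 3) to 2197 (P1 heart pair 5) for the mean, 2103 (P1 heart pair 3) to 3389 (P1 heart pair 5) for equal effects, 749 (P1 heart pair 3) to 2040 (P1 heart pair 5) for the age difference in heart and 50 to 220 (6W muscle pairs 4 and 5) for that in muscle. Other pairs that moved a count by over 1.5 times were P1 heart 2 (1192) and 3 (984), P1 lung 8 (1003), P6 muscle 1, 2 and 5 (83, 86 and 71), 6W heart 1 and 4 (36 and 38) and 6W muscle 2 and 3 (447 and 403). For the age difference they were 6W heart 2 (812), P6 muscle 1, 2 and 5 (148, 143 and 116) and 6W muscle 2 and 3 (142 and 118). Age within a fraction ranged from 6562 to 7094 in heart and 5635 to 5990 in muscle for TdTomato- cells, and from 5624 to 6842 and 4199 to 4638 for TdTomato+ cells. Depth limits the folds of rare transcripts: in P1 heart, 66 of 666 called genes at least 2-fold different had no count in 1 fraction.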

Other observations

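The genes of the next paragraph were chosen after their values were seen, and the splits were set after the result for the 5 combinations, the mean effect and the age differences of the effect, but before it for the test of equal effects and for age within a fraction.

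Lrg1 and Eps8l2 were the 2 genes called in all 5 combinations, and both changed direction between tissues. Lrg1, which encodes a secreted leucine-rich glycoprotein and stands in the venous list, was lower in TdTomato+ cells of P1 heart (log2 fold change -2.43 ± 0.42, SE), where it was barely expressed (0.90 against 4.31 CPM). It was higher in P1 lung (0.99 ± 0.24), P6 muscle (1.91), 6W heart (1.39) and 6W muscle (1.58), with a heart difference between ages of 3.83 ± 0.48 (adjusted p = 2.73e-05; edgeR quasi-likelihood, Benjamini-Hochberg). Eps8l2 (chromosome 7, 141339002 to 141363016), which encodes an actin regulator related to Eps8, was higher in TdTomato+ cells of P1 heart (0.90 ± 0.18) and P1 lung (0.48) and lower in P6 muscle (-1.18 ± 0.15), 6W heart (-0.66) and 6W muscle (-0.76; adjusted p = 1.67e-06 for equal effects). Apoe, the apolipoprotein E gene, was 117 against 736 CPM in P1 heart (log2 fold change -2.65 ± 0.14) and higher in P1 lung (1.33 ± 0.12), P6 muscle (1.03 ± 0.12) and 6W heart (0.53 ± 0.12), and had the smallest p of all genes in the test of equal effects (adjusted p = 7.3e-12). Leaving out 1 pair ended the call of Lrg1 in 6W heart without pair 2 (1.24), of Eps8l2 in P1 lung without pair 7 or 8 (0.31 and 0.35) and of Eps8l2 and Apoe in 6W heart without pair 1, 2, 4 or 6 (-0.69 to -0.62 and 0.36 to 0.60).

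Of the genes higher in TdTomato+ cells of P1 heart, 168 were lower in those of 6W muscle and 41 higher in both, where independent lists would share 41.6 and 20.6. Across genes, which are not independent replicates, the log2 fold changes of these combinations had a correlation of -0.02. Mitochondrial reads were more frequent in the TdTomato+ library in 5 of 5 pairs of P1 lung (0.604% against 0.412%; exact sign-flip permutation p = 0.0625, the smallest 5 pairs allow) and less frequent in 4 of 4 pairs of 6W muscle (0.442% against 1.06%; exact p = 0.125, the smallest 4 pairs allow).

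Chance was tested by regrouping the libraries of each comparison alone into other splits and counting called genes. The real split was the only 1 with as many genes in P1 heart (457 genes, highest other 2, 32 splits), P1 lung (828 and 663, 100 splits), P6 muscle (471 and 2, 100 splits) and 6W muscle (1184 and 0, 32 splits). In 6W heart, 2 of 100 splits, the real one with 27 genes included, gave as many, and the highest other had 286. That split parted pairs 1, 2 and 4 of one sequencing run by fraction and kept pairs 5 and 6 of the other run whole. The replicate block takes whole pairs out of the effect. This split is therefore the fraction contrast in pairs 1, 2 and 4 and not a regrouping by chance. Without pairs 5 and 6, 367 genes were called between the fractions of 6W heart. In P1 lung the split with 663 genes parted pairs 6, 7 and 8 by fraction and kept pairs 1 and 5 whole. It is likewise the fraction contrast in pairs 6, 7 and 8. Among the splits that part every pair, as the real one does, the highest other count was 2 genes in P1 heart (8 splits), 0 in P1 lung (14) and P6 muscle (13), 2 in 6W heart (14) and 0 in 6W muscle (8). These splits are the ones comparable with the real one and are too few for a share under 0.05; the others kept some pairs whole.

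The real split was also the only 1 with as many genes for the mean effect (1323 genes, highest other 310) and the test of equal effects (2641 and 0). Each had 21 splits, too few to exclude chance. Over 100 splits each, the real split was again the only 1 with as many genes for the age difference of the effect in heart (557 and 347) and in muscle (785 and 1). It held for age in TdTomato- cells of heart (6780 and 3152) and muscle (6193 and 1566) and in TdTomato+ cells of heart (5149 and 1317) and muscle (6687 and 2180). The other splits mixed the real ages, so the differences between ages widened the spread within their groups. Their median count was 0 in each of these tests. The larger count of the real split therefore does not exclude chance.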
